A study of Homo sapiens with 31 samples.

How the data were processed

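RNA sequencing of human heart cells was analysed, in 31 libraries that fall into 8 groups. In the first experiment (15 libraries), adult cardiac fibroblasts at 0% or 10% oxygen were cultured either alone or beside fibroblasts held at the other oxygen level. In the second experiment (16 libraries), fibroblasts at 0% oxygen and cardiac myocytes derived from induced pluripotent stem cells at 10% oxygen were cultured alone or beside each other. Per the labels' protocols, the cells sat on fibronectin-coated silicone devices that delivered each gas with 5% carbon dioxide for 24 h in medium with 0.1% serum. Fibroblasts were seeded at 22500 and myocytes at 143472 cells per square centimetre, per the labels' protocols. A serum arrest of 48 h before exposure is stated for the first experiment and not for the second. Joined cultures were separated with a razor blade and 4 regions were lysed per device, per the labels' protocols, so a co-culture library holds RNA of the whole region on 1 side of the interface.

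The values used are the signal that the authors deposited, 1 value per gene and library in 1 table per experiment. They are gene counts, not always whole, divided by a size factor per library. This was read from the values: within each table the median ratio of every library to the geometric mean over genes was the same (1.01 in the fibroblast experiment and 1.03 in the myocyte experiment), and low values stepped by 1 amount per library. With a tolerance of 0.02 reads, 64.2% to 67.1% of the low values (between 0.3 and 8) in the fibroblast libraries were whole multiples of that step, and 75.4% to 78% in the myocyte experiment. Alignment used STAR 2.7.8a and Partek on hg38, per the submitters' processing notes. The program that counted reads, its annotation, its use of strand and the filters on genes are not given in the sources used here. Counting strand being unknown, antisense and overlapping genes are treated as uncertain, as are pseudogenes and near-identical copies.

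Values were given for 24242 genes in the fibroblast experiment and 33831 genes in the myocyte experiment. Gene identifiers were matched to GENCODE 29 on GRCh38 for symbols and coordinates (24234 and 33819 matched). Y-linked genes and XIST were left out (51 and 81 genes), which left 24191 and 33750. Replicate 1 of the 10% oxygen control fibroblasts was not analysed here. No 2 replicates were copies: over 45 pairs of libraries within groups, the correlation of log2 values lay between 0.961 and 0.985.

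Each comparison was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1). Genes with a value of at least 1 in as many libraries as the smallest group were tested, and Benjamini-Hochberg (BH) adjusted p below 0.05 was the threshold. Since values were normalised already, no further scaling was applied, and the median fold change over all genes stayed below 0.09 on the log2 scale in every comparison. Fibroblast comparisons used all 15 libraries of their experiment in 1 model with 4 group means. The comparisons of the second experiment used only the 8 libraries compared, because myocytes and fibroblasts differ in most genes. Adjusted p-values in the text are from limma unless another test is named. They measure the spread between these libraries, and whether replicates are separate devices, donors or days is not given in the sources used here.

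The tests, the lists, the marker sets, the rule for naming genes and the alternatives, other than those said to be added, were chosen before the data were examined. The rule names, per comparison, the 8 largest rises and the 8 largest falls among genes with a symbol that pass the threshold, have a mean log2 value of at least 1 and do not overlap between groups (this last condition is dropped for the change of the oxygen effect). For each list it names up to 4 members with the smallest p among those that pass, or up to 2 as values where none passes. It also always gives CA9, VEGFA, COL1A1, ACTA2 and POSTN in fibroblasts and TNNT2, MYH7, NPPA, NPPB and VEGFA in myocytes. The text names some of these and says where a gene lies outside the rule.

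The 22 lists are HIF targets, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, extracellular matrix, collagen modification, matrix proteases and inhibitors, myofibroblast contractile genes, TGF-beta signalling, cytokines and chemokines, interferon-stimulated genes, cell cycle, the unfolded protein and integrated stress response, cholesterol synthesis, secreted growth factors, NRF2 antioxidant targets, metallothioneins, and 5 further lists. Those are myocyte sarcomere, myocyte calcium handling and ion channels, myocyte stress and fetal genes, cardiac transcription factors and fatty acid oxidation. Lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, BH adjusted over the lists of a comparison, and again with the correlation estimated per list. The limma test fry gave a direction. A score per library, the mean log2 value of a list's members, was compared by a two-sided exact permutation test over all splits of the libraries. The 10 marker sets for cell types were read as levels only.

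Whether replicate numbers pair the libraries was checked as the correlation of deviations from the group means (genes with a mean above 20), with at least 3 pairs needed and every pair above 0.1. The numbers in the sample titles paired the fibroblasts in the oxygen comparison of controls (0.15 to 0.26), in the comparison within 0% oxygen (0.18 to 0.39) and across the interface (0.13 to 0.37). By this rule they did not for the comparison within 10% oxygen (lowest 0.08, 2 of 3 pairs above 0.1). Nor did they for the change of the oxygen effect (lowest 0.04, 18 of 21 pairs above 0.1). Most pairs passed in both, so an effect shared by replicates is not excluded there. In the second experiment title numbers did not pair. Blocks of 4 consecutive library numbers in the labels, called library quartets here, paired the fibroblasts (0.12 to 0.42) and the myocytes (0.22 to 0.50). Neither numbering paired myocyte with fibroblast controls. A fit with these blocks is given beside a result where it changes a call or moves a count by over 1.5 times.

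The share of the neighbour's RNA in a co-culture library was estimated from genes at least 64 times higher in the control libraries of the neighbour's cell type, with a mean of at least 1000 there. Each gene's rise over the recipient's controls, divided by the difference between the control groups, gives an implied share, and the median over genes is reported. This share is a percent of the level in the neighbour's controls. It is not the percent of a library's counts, since sums of values differ between the cell types. Alternatives were quantile normalisation, no filter on low values, pseudocounts of 0.1 and 10, limma without the trend, a minimum log2 fold change of 1, replicate blocks, other sets of libraries in the fit, and leaving out each library. For the second experiment they also include testing only genes less than 2 times higher in the neighbour's controls. This limits but does not remove the effect of carried RNA, which can also dilute the recipient's own genes. Subtracting the carried share, and leaving out the libraries with the largest shares, were added after the data were seen. The subtraction took 1 share per library for every gene and did not scale up what remained.

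Sums of values, in M (mega), were 31.9 to 36.7 per fibroblast library and 34.6 to 53.2 in the second experiment. The step of the low values implies 26.9 to 41.1 and 38.3 to 48.4 M reads. Each analysis was tested on simulated data drawn for the real genes. In the simulation of the oxygen comparison of controls (24161 genes), 64% of the genes planted at a log2 change of 1 were recovered and 88% of those at 2. For fibroblasts at 0% oxygen beside others (24163 genes) these were 64% and 90%, and for those at 10% (24161 genes) 61.2% and 76%. For the change of the oxygen effect (24158 genes) they were 52% and 68%, for fibroblasts beside myocytes (27900 genes) 38% and 62%, and for myocytes beside fibroblasts (28156 genes) 32% and 74%. Each gene was drawn independently from its residual spread, without the structure of replicates or quartets. These rates may therefore not hold in the real libraries. A planted share of 5% of the neighbour's RNA was estimated at 4.96% to 5.05% over 190 genes in fibroblasts and at 4.94% to 5.04% over 251 genes in myocytes. The same control libraries entered the planting and the estimate, so this checks the calculation and not its accuracy in real mixtures.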

Results

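RNA was measured in 31 libraries of human heart cells after 24 h at 0% or 10% oxygen. In the first experiment, adult cardiac fibroblasts, the matrix-producing cells of the heart wall, were cultured alone at 0% oxygen (n = 4 libraries) or 10% oxygen (n = 3, replicates 2 to 4; replicate 1 was not analysed here). Further fibroblasts grew on a device where a 0% region (n = 4) adjoined a 10% region (n = 4). In the second experiment, fibroblasts at 0% oxygen were cultured alone (n = 4) or beside myocytes (n = 4), and cardiac myocytes derived from induced pluripotent stem cells were cultured at 10% oxygen alone (n = 4) or beside those fibroblasts (n = 4). Serum arrest of 48 h is stated for the first experiment only. The values are the authors' normalised gene counts, and levels below are means of these.

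In M (mega) of normalised counts, the sums were 34.6 to 34.8 in 0% control fibroblasts, 34.3 to 36.7 in 0% fibroblasts beside 10%, 32.1 to 32.6 in 10% controls and 31.9 to 33.5 in 10% fibroblasts beside 0%. The reads implied by the values were 31.8 to 34.9, 31.1 to 41.1, 33.9 to 37.6 and 26.9 to 38.3 M in the same order. In the second experiment, the sums were 48.2 to 51.6 M in control fibroblasts, 48.6 to 53.2 M in fibroblasts beside myocytes, 34.9 to 36.7 M in control myocytes and 34.6 to 39.3 M in myocytes beside fibroblasts. The implied reads were 43.7 to 46.9, 42.8 to 47.6, 38.3 to 48.4 and 38.3 to 47.7 M. In a principal component analysis, the first component held 49.7% of the variance of the fibroblast experiment and separated the oxygen levels. It held 87.7% in the second experiment, where it separated the cell types. The second component of the fibroblast experiment (12.1%) fell with the replicate number in each of its groups.

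Markers of 10 cell types were read as levels, and the highest gene of a set does not by itself show that cell type. All 11 fibroblast markers reached a mean of 10 in control fibroblasts of the first experiment, led by COL1A2 (208700 at 0% oxygen), while TTN led the myocyte markers at 523. The leading smooth muscle and pericyte marker there was NOTCH3 (13960), the leading leukocyte marker CD68 (4191), the leading endothelial marker TEK (1887) and the leading endoderm marker SOX17 (1541). TBX18 led the epicardial set (1179), TUBB3 the neural set (1040), POU5F1 the pluripotent set (93.5) and MYH3 the skeletal muscle set (46.6). Set medians in these 0% controls were 528 for neural, 518 for endothelial, 279 for smooth muscle and 191.5 for epicardial markers. They were 28.2 for skeletal muscle, 28.0 for leukocyte and 22.7 for endoderm markers, and 1 of 8 pluripotent markers was measured. In control myocytes, all 15 myocyte markers reached 10, led by ACTC1 (548400), and so did 8 of 11 fibroblast markers, led by COL1A2 (5864). Their highest smooth muscle marker was CNN1 (20490), with CKM for skeletal muscle (9030), KRT19 for the epicardium (1668), POU5F1 for pluripotent cells (1131), KDR for endothelium (624), MAP2 for neurons (535), APOA1 for endoderm (209.9) and CD14 for leukocytes (8.79). NOTCH3, TUBB3 and TEK also led their sets in control fibroblasts of the second experiment (29640, 6301 and 5080).

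The first comparison asks how cardiac fibroblasts respond to 0% oxygen when the whole culture is at that level. Oxygen changed genes of many functions. Genes of the hypoxia response, sugar breakdown, collagen maturation and TGF-beta signalling rose, and antioxidant genes and respiratory chain genes of the mitochondrion tended lower, the last 2 not with an estimated correlation. Of 24166 genes tested, 6124 passed at a BH adjusted p below 0.05 in limma, 3129 higher and 2995 lower at 0% oxygen. Changes of 2-fold or more were mostly rises (837 of 966).

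At a pseudocount of 1, the naming rule put ISM2 first among the rises, a secreted protein gene on chromosome 14 (77474394 to 77498850, GRCh38, GENCODE 29). Its log2 fold change was 6.47 ± 0.41 (SE), with means of 125 (n = 4) and 0.577 (n = 3) and an adjusted p of 5.8e-09 in limma. With so low a level at 10% oxygen the ISM2 value depends on the pseudocount (8.87 at 0.1 and 3.66 at 10, where TCAF2 stood higher at 4.53). The channel regulator TCAF2 (chromosome 7, 143620952 to 143730409) rose by 4.98, from 22.9 to 750. The phosphodiesterase PDE4C (chromosome 19, 18208652 to 18248200) rose by 4.96, from 72.9 to 2262, and the peptide hormone APLN (X, 129645259 to 129654937) by 4.84, from 17.3 to 522. GFRA2 rose by 4.76 and TMEM145 by 4.65. MIR210HG, the host transcript of a microRNA on chromosome 11 (565660 to 568457), rose by 4.61 ± 0.10 (SE), from 64.4 to 1597, with the smallest adjusted p in limma (2.4e-14). TCAF2C (4.96) is a near copy of TCAF2, so its own rise is uncertain. The largest falls were in sparsely expressed genes. FGF12 fell by 2.12 (1.80 at 0% against 8.53 at 10%, limma adjusted p = 0.018), TTLL9 by 1.96 (2.60 against 13.2) and the long noncoding LINC02159 by 2.03. GUSBP16, RIMBP3C, SHLD2P3, GDF5-AS1 and LINC01881 fell by 3.25, 3.08, 3.00, 2.86 and 2.69 but are pseudogenes, near copies or antisense genes, so these values are uncertain.

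Every one of the 26 HIF targets rose (median log2 fold change 2.06, camera adjusted p = 1.4e-38). NDRG1 rose by 3.36 to a mean of 51230 from 4986, BNIP3 by 2.71 to 6585 from 1005 and P4HA1 by 2.75. VEGFA rose by 2.39 (42690 against 8221, limma adjusted p = 4.3e-08) and CA9, a low gene here, by 3.57 (16.2 against 0.642). Of the 20 glycolysis genes 19 rose and 1 fell (median 1.52, 1.9e-27). ENO2 rose by 3.52 (6148 against 535), PGK1 by 2.53, PDK1 by 2.25 and ENO1 by 2.04. The mean HIF score of the libraries was 12.31 ± 0.05 (SD, n = 4) at 0% and 10.10 ± 0.08 (n = 3) at 10% oxygen. The difference of 2.22 had a two-sided exact permutation p of 0.0286, the smallest that 35 splits allow.

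**Figure D1:**
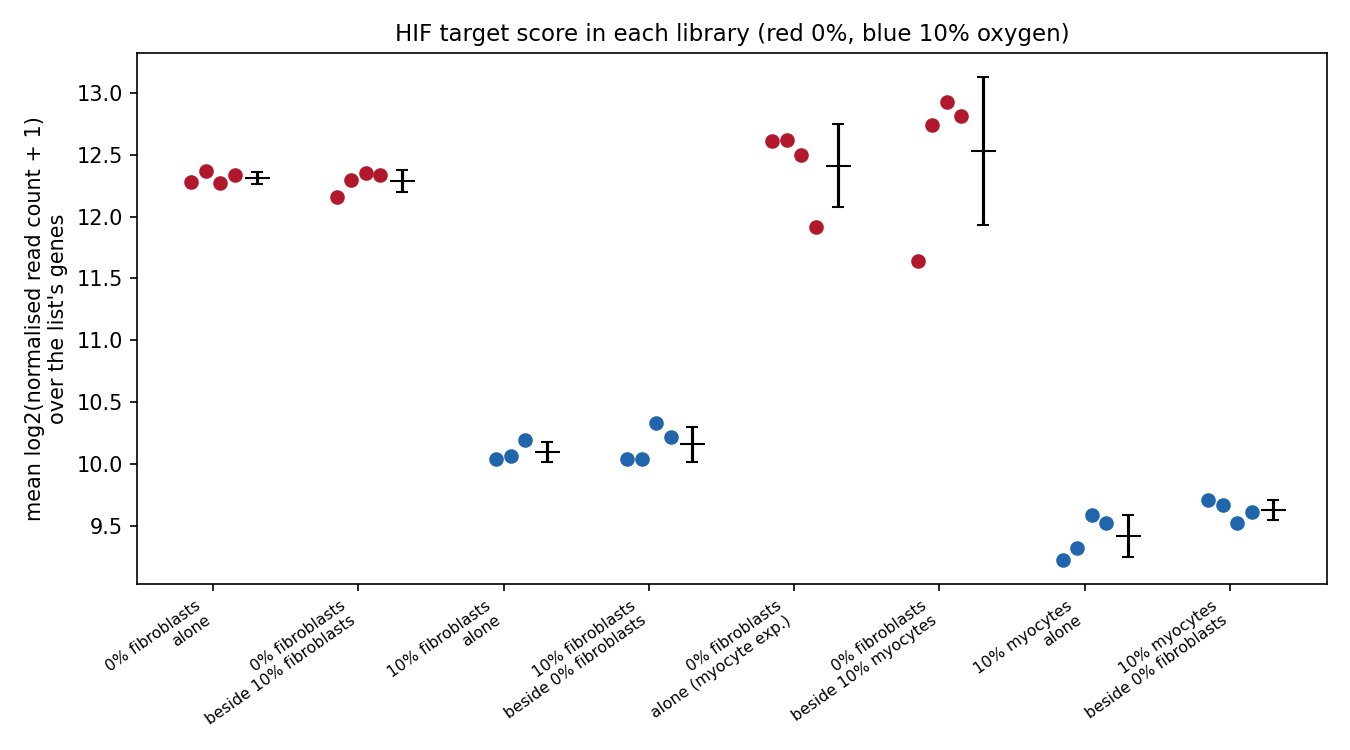
Mean log2 level of the 26 HIF targets in each library (points) of the 8 groups, with the mean and SD; red is 0% and blue 10% oxygen. The 0% fibroblasts of the first experiment average 12.31 alone and 12.29 beside 10% fibroblasts, and the 10% fibroblasts 10.10 alone and 10.16 beside 0%.

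Matrix genes changed in part. Of 22 extracellular matrix genes 9 rose and 0 fell, and 10 rose when adjusted over the list alone, among them THBS2 (0.79), COL5A1 (0.90), COL5A2 (0.47) and COL6A3 (1.07). The list passed (median 0.26, adjusted p = 8.0e-03), though not with an estimated correlation (adjusted p = 0.359). COL1A1 did not change detectably (0.03, limma adjusted p = 0.91). Collagen modification rose as a group, with 9 of 17 members higher (median 0.33, 6.3e-09), including PLOD2 (1.96), LOX (1.91) and LOXL3 (1.37). Of 19 proteases and inhibitors 5 rose and 3 fell, with rises of PLAUR (1.49), TIMP3 (1.36) and ADAMTS4 (1.18). That list missed the threshold (adjusted p = 0.066) but passed with the replicate number as a block (5.1e-03). Of 15 TGF-beta genes 9 rose and 2 fell (median 0.51, 3.1e-03). NOX4 rose by 1.39, TGFB3 by 1.01 and PMEPA1 by 0.92, while TGFB2 fell by 0.70. Of 14 contractile genes 1 rose, and the list did not pass (0.480). ACTA2 was 0.42 higher (limma adjusted p = 0.079) and POSTN 0.26 lower (-0.26, 0.36), and with the block both passed (1.1e-03 and 4.8e-03).

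Respiratory genes tended lower. Of 29 nuclear oxidative phosphorylation genes 2 rose and 8 fell (median -0.08, camera adjusted p = 0.024). NDUFS1 fell by 0.32 and CYC1 by 0.30, while ATP5PO rose by 0.30. Of 13 mitochondrially encoded genes 7 fell and 0 rose, and all 13 fell when adjusted over the list alone (median -0.49, 9.7e-05), with MT-ND2 lower by 0.78 (log2 fold change -0.78) and MT-ND1 by 0.66 (-0.66). Neither list passed with an estimated correlation (adjusted p = 0.374 and 0.365 with an estimated correlation). Of 15 NRF2 antioxidant genes 9 fell and 0 rose (median -0.35, 9.3e-04, and adjusted p = 0.365 with an estimated correlation). SLC7A11 fell by 0.94 and TALDO1 by 0.44. In the stress response list 13 of 18 genes rose and 0 fell (median 0.50, 3.5e-07, and adjusted p = 0.181 with an estimated correlation), with SESN2 (0.67), DDIT3 (0.64) and ATF4 (0.49). Metallothioneins passed (median 0.77, 0.021, and adjusted p = 0.359 with an estimated correlation), with rises of MT1X (1.63) and MT1E (0.98) among 8.

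The other 10 lists did not pass. Of 23 growth factor genes 6 rose and 5 fell (0.187), among them IGFBP3 (3.96, a mean of 29600 against 1905), ANGPTL4 of the HIF targets (3.26) and IGFBP5 (1.77). Of 24 cytokine genes 1 rose and 2 fell (0.463). CCL2 fell by 1.35 and CXCL12 by 0.63, and PTGS2 rose by 1.13 (limma adjusted p = 0.044). Of 20 interferon-stimulated genes 2 fell (0.187), among them IFIT2 by 0.67. Among 17 cholesterol genes 2 rose and 5 fell (0.187), with FDFT1 lower (fell by 0.35). Of 18 fatty acid oxidation genes 2 rose and 4 fell (0.066), with SLC25A20 (fell by 0.80) and CPT1A (fell by 0.63). Cell cycle genes split 3 to 3 of 24 (0.975), and their median (0.01) and mean were above 0 while camera pointed down. Among cardiac transcription factors 1 of 7 rose and 2 fell (0.187), with GATA4 falling by 0.54. Myocyte stress genes gained 2 of 7 rises (0.058), among them XIRP1 (1.93). Of 8 sarcomere genes 0 passed (list 0.463), and of 7 calcium and channel genes 1 fell (0.480). Over all genes, the groups did not overlap in 8072, or 33.4% where chance gives 5.71%. The p-values describe spread between these libraries of 1 experiment.

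The next comparison asks whether the oxygen response keeps its shape where 0% and 10% fibroblasts share a border. It did for most genes called. Hypoxia, glycolysis and collagen-modifying genes were again higher on the 0% side. Of 24166 genes 7071 passed in limma, 3531 higher and 3540 lower at 0%. Of the 6124 genes called alone, 5026 were also called across the border, and all 5026 moved the same way. Over genes called in both, fold changes correlated at 0.978 with a slope of 0.953 (over all genes 0.664), a value across genes, which are not independent replicates.

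APLN rose by 4.88 (678 against 23.1, limma adjusted p = 1.8e-11) and BICDL2 by 4.68. The adipokine LEP (chromosome 7, 128241284 to 128257628) rose by 4.62 (169 against 6.03), and the BMP antagonist NOG (chromosome 17, 56593699 to 56595590) by 4.36 (168 against 7.72). The hormone STC1 (chromosome 8, 23841915 to 23854807) rose by 4.25 to a mean of 38100 against 2146, and VSIG2 rose by 4.40. TCAF2C (4.33) and the pseudogene TCAF2P1 are uncertain. Among falls with a unique identity, IGF1 fell by 2.06 (6.99 against 33.6, limma adjusted p = 7.2e-05) and CCL8 by 2.09 (5.52 against 23.9, 0.012). SMCO3 fell by 2.37 (0.046) and LINC00547 by 1.80 (0.039), both near the threshold. The pseudogenes ST13P13, DDX12P, PHB1P4 and GTF2H2B (falls of 3.22, 2.35, 2.12 and 2.08) are uncertain. CA9 rose by 3.68 and VEGFA by 2.48 (limma adjusted p = 1.2e-05 and 9.3e-09). COL1A1 (0.08, 0.753), ACTA2 (0.34, 0.115) and POSTN (-0.11, 0.697) did not pass, and ACTA2 did with the block (2.9e-04).

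All 26 HIF targets rose (median 1.92, camera adjusted p = 2.7e-35), and 19 of 20 glycolysis genes (1.39, 1.2e-24). Collagen modification gained 10 of 17 rises (0.37, 1.7e-08), and TGF-beta genes 8 rises against 2 falls (0.48, 1.9e-03). These 4 lists also passed with an estimated correlation. Of 29 oxidative phosphorylation genes 14 fell and 0 rose (median -0.17, 8.4e-05, and adjusted p = 0.221 with an estimated correlation), while of 13 mitochondrially encoded genes 0 passed (-0.07, 0.446). Of 15 NRF2 genes 12 fell (-0.50, 3.2e-06, and adjusted p = 0.244 with an estimated correlation). Extracellular matrix (9 rises, 0.33, 1.9e-03), stress response (12 rises and 1 fall, 0.33, 1.1e-04), metallothioneins (3 rises, 0.64, 0.047) and fatty acid oxidation (2 rises and 10 falls, -0.19, 8.7e-03) passed. They did not with an estimated correlation (adjusted p = 0.287, 0.249, 0.382 and 0.166 with an estimated correlation). Proteases passed only with the block (0.147, with the block 0.030). The HIF score differed by 2.13 (exact permutation p = 0.0286, two-sided, the smallest that 35 splits of 8 libraries allow). Groups did not overlap in 6785 genes (28.1%, chance 2.86%).

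**Figure D2:**
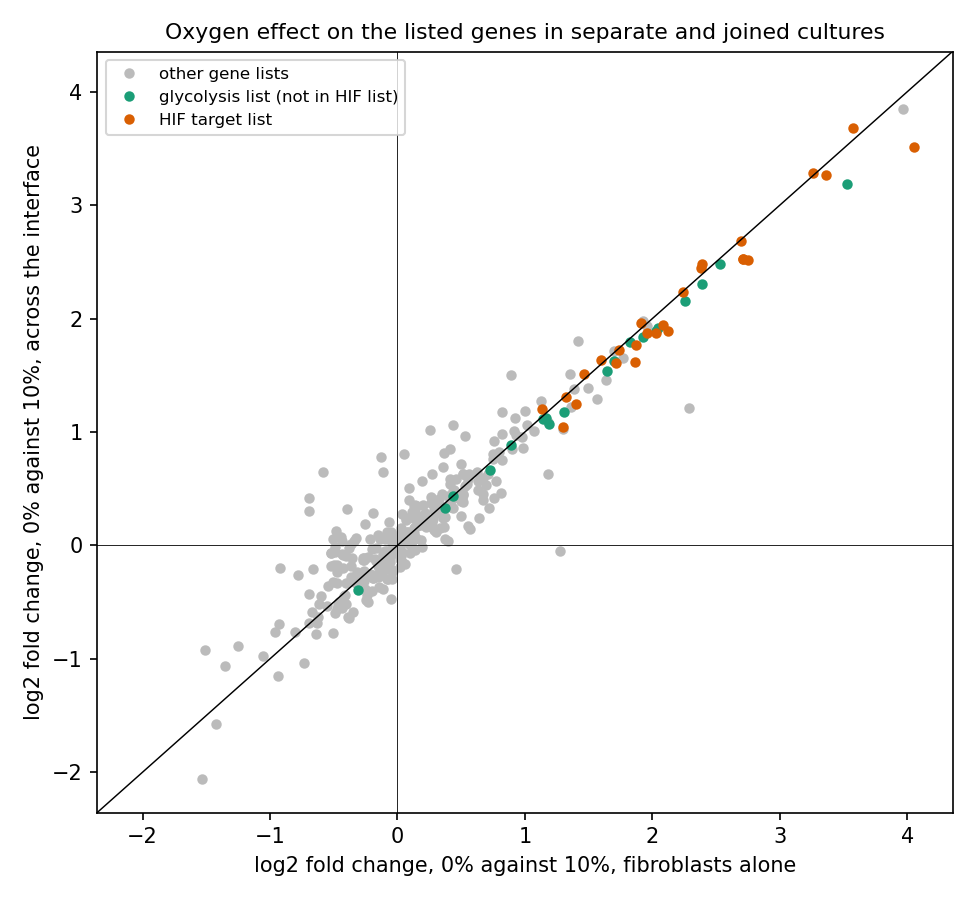
Log2 fold change of 0% against 10% oxygen for the genes of the fixed lists, in fibroblasts cultured alone (horizontal) and across the border (vertical); orange marks HIF targets, green glycolysis, grey the other lists, and the line equality. The slope over all genes called in both comparisons, which are not the genes plotted, is 0.953.

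A direct test asked whether the border altered the oxygen response itself. No single gene passed (0 in limma, 778 with a raw p below 0.05, 359 higher and 419 lower). ENO2 (-0.33), CA9 (0.11) and VEGFA (0.09) had adjusted p near 1, as did NDUFA9 (-0.42), MT-ND3 (0.46), OASL (1.11), HSPA5 (-0.21), TXNRD1 (-0.26) and GCLM (-0.26). Of the lists, 7 passed camera and 0 did with an estimated correlation. The difference between oxygen levels was lower beside the other fibroblasts for 19 of 20 glycolysis genes (median -0.08, 2.0e-03, adjusted p = 0.623 with an estimated correlation). It was higher for 13 of 13 mitochondrially encoded genes (0.44, 6.1e-09, 0.623 with an estimated correlation) and for 20 of 20 interferon-stimulated genes (0.41, 4.9e-03, 0.881 with an estimated correlation). For the mitochondrially encoded genes this was a smaller fall at 0%, with mean scores of 16.14 against 16.62 alone and 16.43 against 16.51 across the border. The interferon score was lower at 0% alone (7.645 against 7.943) and higher across the border (8.748 against 8.535). NRF2 (-0.21, 2.0e-03), oxidative phosphorylation (-0.05, 4.1e-03), stress response (-0.08, 4.9e-03) and HIF targets (-0.09, 0.026) had a lower signed difference, with adjusted p = 0.623 for the first 3 and 0.811 for HIF targets with an estimated correlation. For NRF2 genes the fall at 0% was larger (12.66 against 12.95 alone, 12.44 against 12.92 across the border). For HIF targets the rise was slightly smaller (12.31 against 10.10 alone, 12.29 against 10.16 across the border).

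The question for 0% fibroblasts was whether better oxygenated neighbours alter them. No single gene passed in the fit without the block. Interferon-stimulated and matrix genes leaned up across their lists and antioxidant genes down, though with an estimated correlation no list passed (adjusted p = 0.301, 0.301 and 0.388). Replicate numbers did pair these libraries (0.18 to 0.39), and using them as a block brought some genes past the threshold. In limma 0 of 24166 genes passed (raw p below 0.05 in 2049, 1118 higher and 931 lower). With the replicate number as a block, 246 passed, 174 higher and 72 lower.

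All 20 interferon-stimulated genes were higher (median 1.00, camera adjusted p = 3.5e-13, and adjusted p = 0.301 with an estimated correlation), and 14 passed when adjusted over the list alone. OAS2 was 1.44 higher (limma adjusted p = 0.382, with the block 0.051), OAS3 1.40 (0.368, with the block 0.064) and IFI44L 1.04 (0.483, with the block 0.046). Outside that list, and by the naming rule applied to the fit with the block, EPSTI1 (chromosome 13, 42886388 to 42992271) rose by 1.32 (419 against 157, limma adjusted p with the block 0.014). GBP4 rose by 1.38 (0.027), TNFSF10 by 1.16 (0.038) and CCL5 (chromosome 17, 35871491 to 35880793) by 0.89 (427 against 223, 7.9e-03). OLFML1 (1.64, 0.031) and CLDN1 (0.66, 0.019) rose as well, while RIMBP3C and IFITM4P (2.78 and 2.23) are a near copy and a pseudogene. With the block, NAT16 fell by 1.28, ADAMTS9 by 1.06 (26.2 against 55.6, 0.024), DCAF4L1 by 0.75, KPTN by 0.66, RRAD by 0.58, MIR29B2CHG by 0.57, NEAT1 by 0.54 (23440 against 34490, 0.015) and INSYN2A by 0.53. The interferon score, tested after the values were seen, averaged 8.75 ± 0.95 (SD, n = 4) against 7.65 ± 0.32 (n = 4), with an exact permutation p of 0.0286, two-sided and the smallest possible. Replicate 4 beside 10% fibroblasts was highest (10.1), and without it the difference fell from 1.10 to 0.64.

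**Figure D3:**
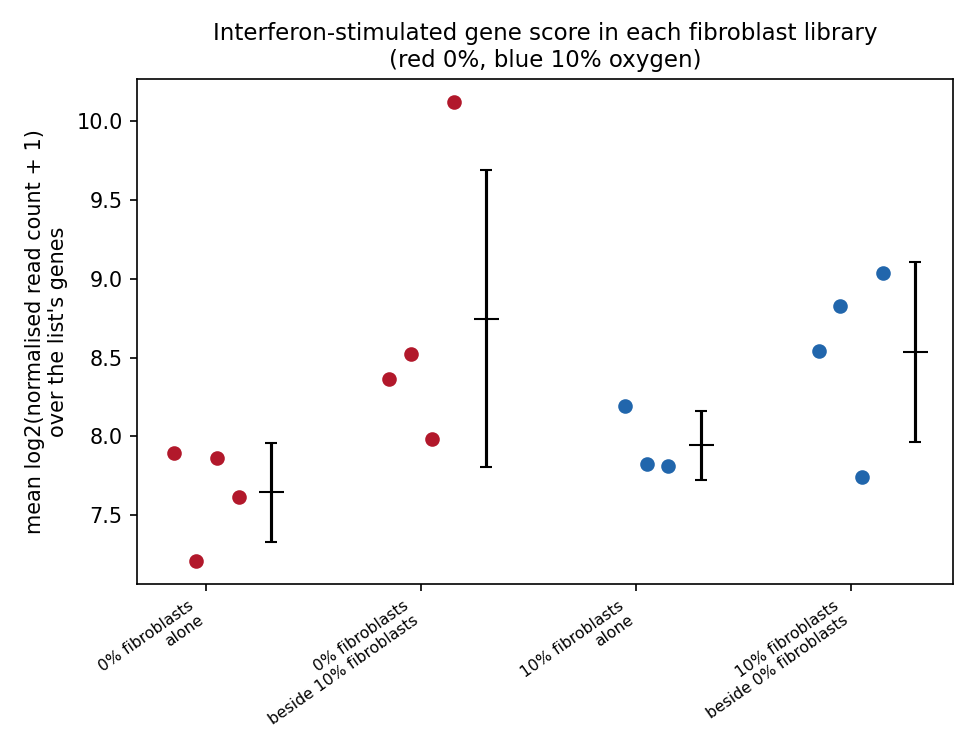
Mean log2 level of the 20 interferon-stimulated genes per library (points) in the 4 fibroblast groups, with mean and SD. Libraries at 0% beside 10% fibroblasts lie at 7.98 to 10.1, and 0% controls at 7.21 to 7.90.

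All 22 extracellular matrix genes were also higher (median 0.16, 7.2e-07, and adjusted p = 0.301 with an estimated correlation). POSTN (0.43), TNC (0.35), COL6A3 (0.60), THBS2 (0.23) and THBS1 (0.45) passed with the block (limma adjusted p = 0.013, 0.014, 0.018, 0.024 and 0.040) and not without it. All 13 mitochondrially encoded genes were higher (0.30, 7.2e-07, adjusted p = 0.461 with an estimated correlation), for example MT-CO3 (0.33, limma adjusted p = 0.496). Of 15 NRF2 genes 14 were lower (-0.24, 3.0e-06, adjusted p = 0.388 with an estimated correlation). SLC7A11 (-0.39) and SRXN1 (-0.34) passed with the block (0.025 and 0.030). Stress response genes (-0.07, 0.042), with ATF3 at -0.36, and fatty acid oxidation (-0.07, 0.030), with CD36 at -0.27 (limma adjusted p = 0.92, with the block 0.025), were lower, with 0.670 and 0.301 under an estimated correlation. HIF targets did not shift (-0.02, 0.519), with LOX at 0.27, KDM3A at -0.15, CA9 at 0.27 (0.917) and VEGFA at -0.03 (0.982). COL1A1 (0.18) and ACTA2 (0.16) did not pass. Cell cycle, cholesterol synthesis and cardiac transcription factors passed camera only with the block (0.017, 0.017 and 0.036). The HIF score was 12.29 against 12.31 (exact permutation p = 0.714, two-sided, n = 4 and 4). Groups did not overlap in 1144 genes (4.73%, chance 2.86%).

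For 10% fibroblasts the question was the reverse, whether hypoxic neighbours change them. A single gene passed, and whole lists moved slightly. Interferon-stimulated, matrix and nuclear oxidative phosphorylation genes leaned up and cholesterol genes down, though with an estimated correlation no list passed (adjusted p = 0.756, 0.506, 0.506 and 0.582). In limma 1 of 24166 genes passed (raw p below 0.05 in 1406, 746 higher and 660 lower). It was NPIPB5 (chromosome 16, 22479121 to 22536521), which fell by 0.44 ± 0.06 (SE), 3040 against 4128 (limma adjusted p = 0.034). NPIPB5 belongs to a family of near copies, so its value is uncertain. With the replicate number as a block 10 genes passed, 4 higher and 6 lower.

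Of 20 interferon-stimulated genes 20 were higher (median 0.43, camera adjusted p = 8.3e-05, and 0.756 with an estimated correlation), for example MX2 (1.33, limma adjusted p = 0.882). Of 20 glycolysis genes 19 were higher by a small amount (median 0.06, 8.6e-04, and 0.536 with an estimated correlation), ENO2 by 0.37 (limma adjusted p = 0.609) and ENO1 by 0.16 (0.828). HIF targets missed the threshold (0.05, 0.075), with FAM162A at 0.24, BNIP3 at 0.18, CA9 at 0.16 (0.987) and VEGFA at -0.12 (0.973). Of 22 matrix genes 20 were higher (0.14, 8.3e-05), with VCAN at 0.36, THBS2 at 0.21, POSTN at 0.28 and COL1A1 at 0.13, and of 17 collagen-modifying genes 12 (0.07, 0.017), with LOXL1 at 0.25. ACTA2 stood at 0.24. The 10% controls lack replicate 1, and the second principal component followed the replicate number. Part of the values without the block may therefore come from unequal replicates. With the block POSTN stood at 0.23, ACTA2 at 0.15, COL1A1 at 0.05, VEGFA at -0.05 and CA9 at 0.19. The HIF list passed with it and the cell cycle list did not, though these libraries did not pair by the rule. Of 29 oxidative phosphorylation genes 25 were higher (0.07, 2.1e-04), NDUFA9 by 0.28, while mitochondrially encoded genes were lower without passing (-0.12, 0.052). The matrix, collagen and oxidative phosphorylation lists had 0.506 with an estimated correlation. Of 24 cell cycle genes 21 were higher (0.15, 0.010, and 0.826 with an estimated correlation), MCM2 by 0.15. All 17 cholesterol genes were lower (-0.10, 8.3e-05, and 0.582 with an estimated correlation), FDPS at -0.16 and MSMO1 at -0.18. The HIF score was 10.16 against 10.10 (exact permutation p = 0.486, two-sided, n = 4 and 3). Groups did not overlap in 1606 genes (6.65%, chance 5.71%).

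In the second experiment, 0% fibroblasts were compared beside and without 10% myocytes. Most of the change was the appearance of myocyte transcripts, in uneven amounts between replicates. Genes that fibroblasts express themselves changed less, with antioxidant genes leaning down (camera adjusted p = 1.5e-03, but 0.815 with an estimated correlation). In limma 0 of 29415 genes passed (raw p below 0.05 in 1989, 1352 higher and 637 lower, smallest adjusted p = 0.332). With library quartets as a block 29 passed, 28 higher and 1 lower.

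Of the 28 rises under the block 25 were 2-fold or more, and the largest were myocyte genes. PLN rose by 7.02 (5931 ± 6654 (SD, n = 4) against 24.6, limma adjusted p with the block 0.023), ACTC1 by 6.96 (61160 ± 66170 (SD) against 218), MYL7 by 6.90, TNNI1 by 6.74, SMYD1 by 6.70, NPPA by 6.70, MYH7 by 6.67 and CSRP3 by 6.67. MYBPC3 (6.51) and MYH6 (6.24) also rose. The 3 smaller rises, given after their values were seen, were PLXDC1 (0.76), SESN3 (0.63) and a gene without a symbol (ENSG00000284874, 0.59). The 1 fall was VIPR1, a receptor gene on chromosome 3 (42489299 to 42537573), by 0.57 (1363 against 2014, limma adjusted p = 0.497, with the block 0.048). All 18 sarcomere genes were higher (median 5.63, camera adjusted p = 2.3e-22), all 10 cardiac transcription factors (1.15, 2.7e-06; NKX2-5 5.59), 14 of 15 calcium and channel genes (1.24, 1.3e-08), 7 of 9 stress and fetal genes (3.26, 1.3e-04), 28 of 29 oxidative phosphorylation genes (0.18, 3.5e-06; ATP5PO 0.24) and 17 of 19 fatty acid oxidation genes (0.07, 0.011; PPARGC1A 5.92). Contractile genes (15 of 15, 0.17, 5.0e-04; MYH11 0.85, LMOD1 0.75) leaned up too. With an estimated correlation these 7 lists had an adjusted p of 0.472. With each library's myocyte share subtracted, none of the following lists passed and their medians turned negative. They were sarcomere (-1.05), calcium and channel (-0.13), oxidative phosphorylation (-0.11), fatty acid oxidation (-0.14) and cardiac transcription factor genes (-0.67). The subtraction did not scale up the fibroblast part that remained, which by itself lowers unchanged genes in libraries with a large share. Small negative medians after it are therefore not read as falls.

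The 190 genes at least 64 times higher in myocytes gave the myocyte share of each library. As a percent of the level in control myocytes, it was 19.6%, 0.625%, 0.334% and 12.8% in replicates 1 to 4 beside myocytes. The 15 myocyte markers alone gave 21.1%, 0.565%, 0.395% and 12.02%. Averaged over the 4 libraries, 100% of the 190 genes had a share above 0, and in replicates 2 and 3 alone 95.3% and 91.1% did. When only genes less than 2 times higher in control myocytes were tested with the block, 16 passed, 8 higher and 8 lower. Among them, chosen after their values were seen, PLXDC1 (0.76), TMEM119 (0.71), SESN3 (0.63) and RRAD (0.60) rose. ARC fell by 2.10, EREG by 0.97, SLC7A11 by 0.79 and VIPR1 by 0.57. Carried myocyte RNA dilutes fibroblast genes, so part of such falls could come from it.

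**Figure D4:**
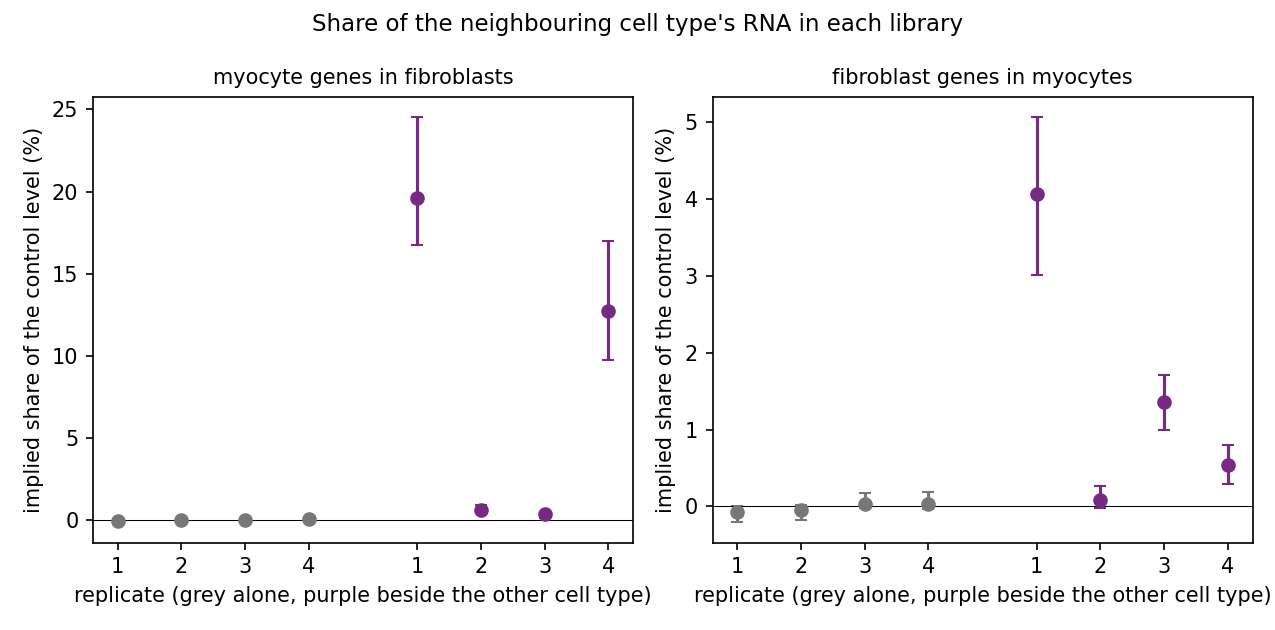
Share of the neighbour's RNA per library, as the median (point) and quartiles (bars) over genes at least 64 times higher in the neighbour's cell type; grey is cultured alone, purple beside the other type. Fibroblast libraries beside myocytes reach 19.6%, and myocyte libraries beside fibroblasts 4.06%.

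All 15 NRF2 genes were lower in fibroblasts beside myocytes (-0.21, 1.5e-03, adjusted p = 0.815 with an estimated correlation and 0.111 with the myocyte share subtracted), with SLC7A11 at -0.79 (limma adjusted p = 0.332) and SRXN1 at -0.42 (0.694). Extracellular matrix (21 of 22 higher, 0.14, 0.044) and mitochondrially encoded genes (13 of 13, 0.14, 0.029) passed, with 0.901 under an estimated correlation. The mitochondrially encoded list turned slightly negative with the myocyte share subtracted (-0.0924), which is not read as a fall, since the remainder was not scaled up. TGF-beta genes (0.115; TGFB3 0.58) and metallothioneins (-0.26, 0.086; MT1G -1.34) passed only with the block (0.037 and 5.3e-03). POSTN (0.25), COL1A1 (0.29), ACTA2 (0.49), VEGFA (-0.10) and CA9 (0.57) did not pass. HIF targets did not shift (median -0.01 but mean 0.12, 0.948), though EGLN3 stood at 2.98 (limma adjusted p = 0.409). The HIF score was 12.53 ± 0.60 (SD, n = 4) against 12.41 ± 0.33 (n = 4), with an exact permutation p of 0.629, two-sided. Groups did not overlap in 1173 genes (3.99%, chance 2.86%).

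The matching question for 10% myocytes was what 0% fibroblasts next to them change. A small set of genes rose, led by SOCS3, a feedback inhibitor of cytokine signalling, with the interferon-related IFI16 and IRF9. Cytokine and interferon lists were higher, though not with an estimated correlation (adjusted p = 0.237 for both), and sarcomere genes showed no single change. In limma 8 of 28735 genes passed, 7 higher and 1 lower (raw p below 0.05 in 1431). With library quartets as a block 71 passed, 66 higher and 5 lower.

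SOCS3 (chromosome 17, 78356778 to 78360077) rose by 2.07 ± 0.16 (SE), 1043 ± 254 (SD, n = 4) against 243 ± 29.1 (n = 4), with a limma adjusted p of 2.1e-03. The sodium channel SCN9A (chromosome 2, 166195185 to 166376001) rose by 1.76 (132 against 37.0, 0.025). CPNE5 (chromosome 6, 36740775 to 36840002) rose by 1.18 (640 against 282, 6.6e-03) and IFI16 (chromosome 1, 158999968 to 159055155) by 1.15 (700.1 against 316, 6.6e-03). IRF9 (chromosome 14, 24161053 to 24166565) rose by 0.99 (472 against 236, 0.020). MAN1C1 (chromosome 1, 25617468 to 25786207) rose by 0.84 (3066 against 1713, 0.040), and PLEKHA4 (chromosome 19, 48837097 to 48868632) by 0.53 (837 against 578, 0.040). The 1 fall was a gene with a clone-based name, outside the naming rule and given after its values were seen (-4.36, 3.0e-03). Without 1 library at a time the count lay between 4 and 36. It was 36 without replicate 2 beside fibroblasts, 4 without replicate 3 beside fibroblasts or control replicates 1, 2 or 4, and 5 without control replicate 3.

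**Figure D5:**
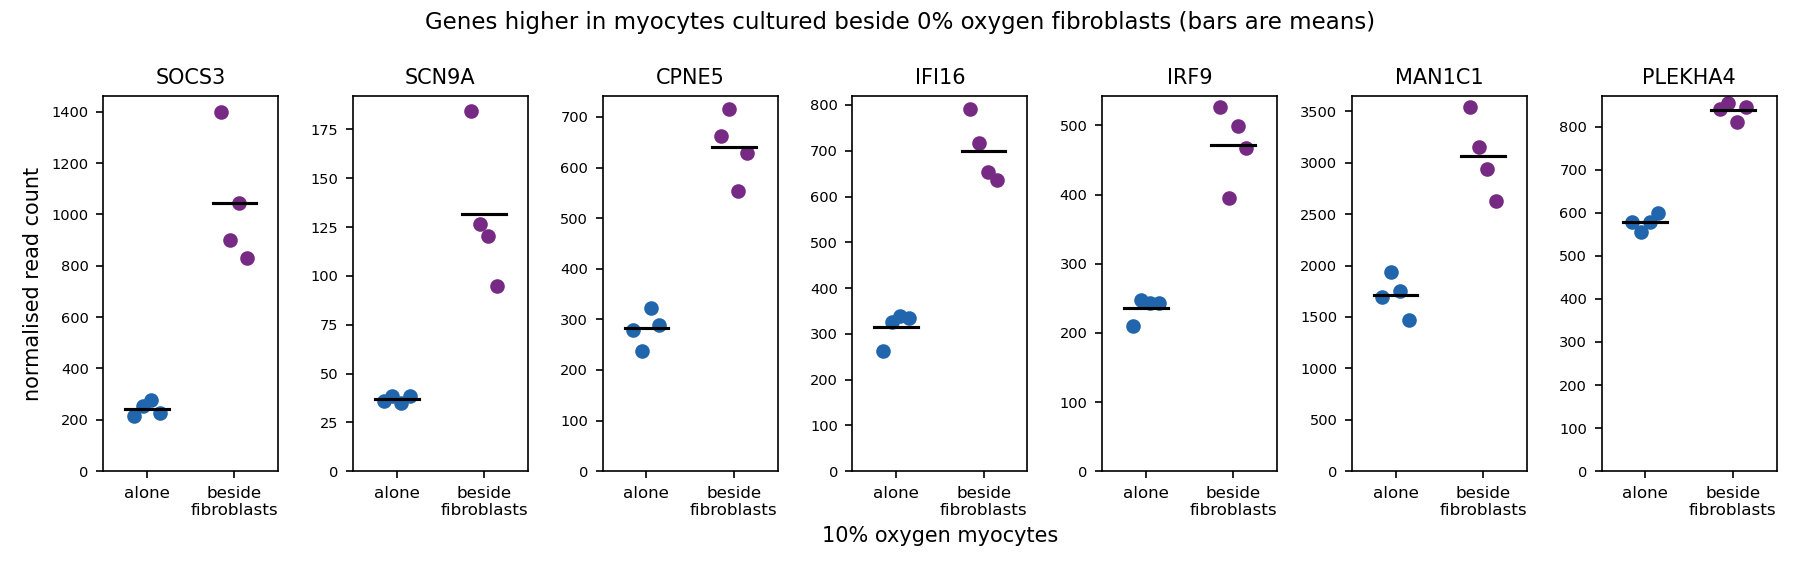
Normalised counts of the 7 named genes called higher in 10% myocytes beside 0% fibroblasts, per library (points) with group means (bars). SOCS3 averages 1043 beside fibroblasts and 243 alone.

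With the block, further rises were STAT3 (0.87, 7543 against 4101, limma adjusted p = 0.122, with the block 4.8e-04), CEBPD (0.88, 0.111, with the block 2.3e-03), A2M (1.14, with the block 7.1e-03), FNDC5 (1.76, with the block 4.5e-05), PTP4A3 (0.96, with the block 5.4e-04) and BANCR (1.45). These 6 were chosen after their values were seen. The naming rule picks genes that fibroblasts express far more, SRGN (7.03), MGP (5.81), THBS2 (5.60), BGN (5.49), ESM1 (4.47), ANPEP (4.33), MMP1 (4.14) and PSMB8 (3.05). The fibroblast share, from 251 genes, was 4.06%, 0.0863%, 1.36% and 0.536% in replicates 1 to 4 beside fibroblasts. At these shares carried RNA would equal 91.6% of the rise of SRGN, 62.6% for MGP, 104.5% for THBS2, 80.4% for BGN, 39.7% for ESM1, 62.4% for ANPEP, 46.1% for MMP1 and 65.7% for PSMB8, and 169.7% for HMOX1 below. For the 7 genes called higher without the block its median was 7.15%, and the highest was SCN9A (40.3%).

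All 15 cytokine genes tested were higher (median 1.04, camera adjusted p = 7.2e-10, and adjusted p = 0.237 with an estimated correlation), 8 of them when adjusted over the list alone. ICAM1 was 1.97 higher (limma adjusted p = 0.074, with the block 0.010). Of 17 interferon-stimulated genes 16 were higher (0.71, 1.2e-07, and 0.237 with an estimated correlation), with IFIT2 at 2.65 (0.636) and OAS3 at 2.28 (0.371). Fewer than 5 members of either list were under 2 times higher in fibroblasts, so neither could be tested on such genes, which carried RNA moves least. With the fibroblast share subtracted both passed (9.6e-07 and 1.1e-04), but not with an estimated correlation (0.395). Matrix (21 of 22, 1.53, 1.4e-13), proteases (18 of 19, 0.51, 2.1e-07) and growth factors (21 of 23, 0.20, 1.6e-03; IGF1 1.96) were higher, with 0.269, 0.385 and 0.237 under an estimated correlation. So were collagen modification (17 of 17, 0.22, 7.7e-05) and TGF-beta genes (12 of 15, 0.18, 2.2e-03), both 0.551 with an estimated correlation. With the fibroblast share subtracted none of these 5 passed (0.271, 0.164, 0.732, 0.663 and 0.645), and growth factors turned down by their mean (-0.0968). HIF targets passed (19 of 26, 0.06, 0.015), with NDRG1 at 0.59 and BHLHE40 at 0.85, but not with the block (0.081) or an estimated correlation (0.551). With the share subtracted their median turned negative (-0.11, 0.078, with the block 0.024), which is not read as a fall. The share subtracted averaged 1.51% for every gene. NDRG1 (0.244%), ANGPTL4 (0.271%) and LOX (0.826%) implied far less, so more than their rise was removed, while STC2 implied 1.42%. Sarcomere genes passed only with the block (-0.10, 0.060, with the block 0.014). HMOX1 (1.55), FHL2 (0.33) and SLC2A3 (0.31) passed with the block (limma adjusted p = 0.032, 0.048 and 0.044). TNNT2 (-0.09), MYH7 (-0.21), NPPA (-0.07), NPPB (-0.11), TTN (-0.30), KCNQ1 (0.41) and VEGFA (0.08) did not pass. The HIF score was 9.63 ± 0.08 (SD, n = 4) against 9.41 ± 0.17 (n = 4), with an exact permutation p of 0.0857, two-sided, where 0.0286 is the smallest possible. That test does not use the library quartets, and within each quartet the library beside fibroblasts had the higher score. Carried fibroblast RNA was not removed from these scores. Groups did not overlap in 887 genes (3.09%, chance 2.86%).

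The last comparison sets 10% control myocytes against 0% control fibroblasts, to show cell identity. Cell type and oxygen differ together here and cannot be separated. Sarcomere, mitochondrial and cell cycle genes were higher in myocytes, and matrix, hypoxia and antioxidant genes lower, though with an estimated correlation 0 of 22 lists passed. In limma 18834 of 29883 genes passed, 9752 higher and 9082 lower, with 12729 changed 2-fold or more. MYH7 (chromosome 14, 23412738 to 23435718) was higher by 12.08 (203300 against 79.4), MYL7 by 11.98, SMYD1 by 11.93, MYBPC3 by 11.86, LRRC10 by 11.67, NPPA by 11.63, ACTC1 by 11.62 (548400 against 218) and GUCY1A1 by 11.58. TNNT2 stood at 9.004 and NPPB at 8.29. Fibroblast genes fell to low levels, with SRGN at -14.36, THBS2 at -13.04, MGP at -12.98, ELN at -12.98, DCN at -12.92, BGN at -12.51, FAP at -12.49, GREM1 at -12.18, COL1A1 at -8.79 (2164 against 883200) and POSTN at -7.63. ACTA2 was higher in myocytes by 1.55, and VEGFA (-3.22) and CA9 (-2.39) were lower.

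Of 22 lists 21 passed camera. All 18 sarcomere genes were higher in myocytes (median 10.76, 1.3e-10, and adjusted p = 0.123 with an estimated correlation). So were 11 cardiac transcription factors (5.09), among them IRX4 (10.40), TBX5 (6.05), TBX20 (4.43) and GATA4 (3.53), and 12 calcium and channel genes with 2 lower (4.33), with KCNH2 at 10.98 and HCN4 at 10.38. Oxidative phosphorylation had 28 of 29 genes higher (1.21, 3.6e-09, and 0.149 with an estimated correlation), with ATP5F1A at 1.90 and CYC1 at 1.40. All 24 cell cycle genes were higher (1.37, 1.8e-07), with TYMS at 2.68 and MCM3 at 2.17. All 22 matrix genes were lower (-7.10, 5.9e-11, and 0.149 with an estimated correlation). Of 26 HIF targets 24 were lower and 1 higher (-2.69, 3.6e-09, and 0.184 with an estimated correlation), with ANGPTL4 and STC2 (-6.76) far down, and of 15 NRF2 genes 13 were lower (-2.62), with SLC7A11 at -4.85. Contractile genes split 7 to 7 (0.999), with a median of 0.35 and a mean of -0.12. Groups did not overlap in 17524 genes (58.6%, chance 2.86%).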

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

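Libraries were compared within each of 117 groups of 4 values (scores of lists and markers, and fixed genes), and a library was noted where its gap to the nearest of the others exceeded what Dixon's test allows at 95%. In 6 of the 117 it did, and chance alone gives about 1 in 20. No explanation was tested for these, technical or biological.

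In the first experiment, the cardiac myocyte marker score of replicate 3 of the 0% fibroblasts beside 10% fibroblasts was lowest at 3.573, where the others lay at 4.667 to 4.876. The CA9 level of replicate 2 of the 0% controls was 11.78 against 17.41 to 18.2. Both rest on genes at low levels. In 10% control myocytes of the second experiment, the leukocyte marker score of replicate 4 was lowest at 1.324 (others 1.947 to 2.064), also on low genes.

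In 0% fibroblasts of the second experiment, the HIF score of control replicate 4 was 11.92 (others 12.5 to 12.62) and its epicardial marker score 5.732 (others 5.902 to 5.912). Beside myocytes, the HIF score of replicate 1 was 11.64 (others 12.74 to 12.93). Both libraries belong to the same library quartet. Replicate 1 beside myocytes also held the highest myocyte share (19.6%), while control replicate 4 had no neighbour. What lowered the scores was not tested. Without replicate 1 beside myocytes the HIF score difference was 0.417, and without control replicate 4 it was -0.0451.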

How the results depend on the processing

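Tests that subtract the carried share, combine the block with other choices, leave out several libraries, take only genes that could not be carried for the lists, leave out libraries for the interferon score, or block or leave out libraries in the comparison of cell types were chosen after the results were seen. For every count and list below whose value differs from the report, the cause was not tested, except where fewer genes or libraries entered by construction. Of the settings of named genes, 3870 kept their side of the threshold, 108 lost it, 140 gained it and 0 reversed with a call in either fit. Among the 3870, 38 changed sign without a call in either fit, 16 of them on subtraction. For lists the 4 counts were 444, 94, 20 and 12 (by camera direction), with 39 changes of sign of the median. From marker genes alone, all 8 neighbour shares moved by less than the SD of the 4 shares of their group. That bound is wide, because the shares within a group are very unequal, so it says little. The share of replicate 1 of myocytes beside fibroblasts moved from 4.06% to 5.40%. The interferon score, added later, kept its direction throughout.

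Requiring a log2 fold change of at least 1 cut the oxygen counts to 966 genes in controls and 1062 across the border, and the block raised them to 7832 and 8794. Leaving out each library gave 4733 to 5643, 6063 to 6620, and 17881 to 18676 for the comparison of cell types. With an estimated correlation, lists passing went from 10 to 4 in both oxygen comparisons, and to 0 from 6 (0% beside 10%), 7 (10% beside 0%), 7 (change of the oxygen effect), 10 (fibroblasts beside myocytes), 8 (myocytes beside fibroblasts) and 21 (cell types). PTGS2 and IFIT2 lost the threshold in 7 of 14 alternatives each, LINC01881 in 5, FGF12 and GUSBP16 in 4, SHLD2P3 in 3, LINC02159 in 2 and COL5A2 in 1. Across the border SMCO3 lost it in 9 of 15 and LINC00547 in 8.

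With the replicate block by title number, 246 genes passed in 0% fibroblasts beside 10%. Without the block, 0 passed with all libraries or with any 1 left out (0 to 0), and libraries were not left out of the fit with the block. In 10% fibroblasts beside 0%, the numbers did not pair by the rule (2 of 3 pairs above 0.1, and 4 of 6 samples closest to their own number). The block gave 10 genes there in place of 1. With it the HIF list passed (5.5e-03), the cell cycle list did not (0.162) and ENO2 did (0.028). The count there was 0 without the trend, 0 at a log2 fold change of 1 and 0 with only the groups compared. It was 0 without replicates 1 or 3 beside 0%, or without control replicates 2, 3 or 4, and 3 without replicate 4 beside 0%. For the change of the oxygen effect (33 of 42 samples closest to their own number) block and libraries left out gave 0 to 0 genes, and the matrix list passed with the block (5.6e-03). Using only the groups compared is no alternative there. For the genes and lists named in a comparison, and where the numbers pair, the block changed no other call.

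For fibroblasts beside myocytes, 0 became 7 without the trend, 29 with library quartets as a replicate block and 209 with all 16 libraries in the fit. It became 16 with the block and only genes less than 2 times higher in control myocytes. With the block and the carried share subtracted 43 passed, and 3 did without replicates 1 and 4 together. Leaving out each library gave 0 to 0. Lists passing went from 10 to 6 with genes less than 2 times higher in control myocytes and to 6 with the share subtracted. Subtraction, with and without the block, reversed camera direction and median of oxidative phosphorylation (-0.11), mitochondrially encoded genes (-0.0924), cardiac transcription factors (-0.67) and fatty acid oxidation (-0.14). For sarcomere (-1.05) and calcium and channel genes (-0.13) only the median turned. MYH6 (-4.83), MYH7 (-1.95) and MYBPC3 (-1.41) turned too and did not pass, with or without the block. Since the fibroblast part that remained was not scaled up, the small negative medians are not read as falls.

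For myocytes beside fibroblasts, 8 became 4 without the trend, 5 at a log2 fold change of 1 and 0 with the title number as a block (which did not pair). It became 71 with library quartets and 77 with all 16 libraries. With only genes less than 2 times higher in control fibroblasts it was 1, and 111 with those and the block. It was 94 with the block and the share subtracted, and 5 without replicates 1 and 3 together. Leaving out each library gave 4 to 36: 36 without replicate 2 beside fibroblasts, 4 without replicate 3 there or control replicates 1, 2 or 4, and 5 without control replicate 3. SOCS3 lost the threshold in 1 of 19 alternatives, IFI16 in 3, SCN9A in 9, IRF9 in 10 and PLEKHA4 in 12, and of 21 alternatives CPNE5 lost it in 3 and MAN1C1 in 12. Lists went from 8 to 0 with genes less than 2 times higher in control fibroblasts, with and without the block. The cytokine and interferon lists had too few such genes to be tested. The lists went to 2 with the share subtracted and to 4 with that and the block. Subtraction reversed HIF targets (-0.11, with and without the block), growth factors (median 0.0233 but mean -0.0968, and camera pointed down, without the block) and metallothioneins (-0.35, with the block). THBS2 (-1.10), HMOX1 (-1.54) and NDRG1 (-4.13) turned without passing. The same share was taken for every gene, and HMOX1 (0.894%) and NDRG1 (0.244%) implied less, so more than their rise was removed. These turns, and that of HIF targets, are not read as falls.

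HIF score differences without each library were 2.19 to 2.27 in controls (exact permutation p 0.0667 to 0.1, since fewer splits remain), -0.0487 to 0.0149 in 0% fibroblasts, 0.00262 to 0.108 in 10% fibroblasts, 2.09 to 2.19 across the border, -0.0451 to 0.417 beside myocytes and 0.1499 to 0.271 in myocytes. Interferon score differences were 0.643 (without replicate 4 beside 10%) to 1.36 in 0% fibroblasts, with exact permutation p of 0.0571 without any 1 control, and 0.426 to 0.857 in 10% fibroblasts. With the glycolysis list, 10% fibroblasts beside 0% were 0.0809 higher (exact permutation p = 0.0286). With the median of the HIF list, myocytes beside fibroblasts were 0.374 higher (exact permutation p = 0.0286). Depth limits genes of a few reads, where the step from 1 read to the next is large.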

Other observations

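The tests of the genes called higher in myocytes, of genes of hypoxic fibroblasts, of glycolysis genes and of changes shared by both oxygen levels were chosen after the results were seen. The splits of libraries and the tests of the myocyte and fibroblast shares were written before.

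The libraries of each comparison were regrouped in all 35 ways, the real one included. For oxygen in control fibroblasts 1 split of 35 called as many genes (6124, highest other 1844), across the border 1 of 35 (7071, highest other 0) and for the cell types 1 of 35 (18834, highest other 0), so chance can be excluded for these. For 10% fibroblasts beside 0%, 4 of 35 gave at least the 1 called (highest other 3), and for myocytes beside fibroblasts 2 of 35 gave at least 8 (highest other 3372), so chance is not excluded by this test. Where 0 genes were called every split gives as many by construction, so the test says nothing about chance there. This holds for 0% fibroblasts beside 10% (35 of 35, highest other 57), fibroblasts beside myocytes (35 of 35, highest other 470) and the change of the oxygen effect (100 of 100 drawn, highest other 2499). The split with 57 parts replicates 1 and 2 from replicates 3 and 4. The splits with 470 and 3372 follow library quartets and point to a structure of the libraries, and with quartets as a block the real counts were 29 and 71. With the block only 8 swaps within pairs exist, too few for a share under 0.05. The real one was 1 of 8 each time, with 7832 against a highest other of 3740 for oxygen, 246 against 1, 8794 against 0 across the border, 29 against 0 and 71 against 0.

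Myocyte genes in fibroblasts beside myocytes, and fibroblast genes in myocytes beside fibroblasts, may be RNA or cells carried over when the regions were parted. Carried RNA raises each gene by the same share of its level in the neighbour. Implied shares were averaged over the 4 libraries of a group, so libraries with large shares weigh most. Libraries with small shares were less uniform. In fibroblast replicates 2 and 3 beside myocytes, 95.3% and 91.1% of genes lay above 0 (quartiles of replicate 3 0.138% to 0.4825%). In myocyte replicate 2 beside fibroblasts 69.7% did, with a lower quartile of -0.0235%. For the averages, the upper quartile was 1.41 times the lower one in fibroblasts (7.29% to 10.3%, 100% of 190 genes above 0). It was 1.57 times in myocytes (1.20% to 1.88%, 99.6% of 251 genes), as carrying over would give. Migrating cells of the other type could give a similar pattern and were not tested. The patterns would differ for genes raised at 0% oxygen if moved fibroblasts lost that rise. In myocytes beside fibroblasts, NDRG1 (0.244%), ANGPTL4 (0.271%), PDE4C (0.270%) and APLN (-0.415%) implied shares below the lower quartile. ADAMTS4 (2.95%), LOXL3 (1.51%) and STC2 (1.42%), also raised at 0% oxygen, lay above it, so the source stays open. These genes were picked after their values were seen. Shares in control libraries lay between -0.0674% and 0.0477%. They centre near 0 by construction, since the same libraries set the baseline, so they are no independent measure of noise.

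Carried RNA or cells could explain some of the genes called higher in myocytes beside fibroblasts. Over the 7 genes called without the block it would give a median of 7.15% of the rise (lowest 0.0232%, highest 40.3% for SCN9A), which argues against it as their whole source. Over all 66 called with the block the median was 5.23%, but for 13.6% of them it would give at least 50% of the rise. Among these were THBS2 (104.5%), SRGN (91.6%) and BGN (80.4%), which carried RNA could explain. For CA12 (406.3%) and HMOX1 (169.7%) it would give far more than the rise, so 1 common share does not describe them. Of the 66, 34 are less than 2 times higher in fibroblasts. Their median of 0.302% (highest 8.99%) says nothing more, since that choice of genes keeps it low. What raised the others stays open, since chance is not excluded for these counts. Each library quartet holds 1 myocyte library of either group, and with quartets as a block all 8 genes still passed, which argues against the quartets as the source.

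In 10% fibroblasts beside 0%, 19 of 20 glycolysis genes were slightly higher, which could come from a little carried RNA of 0% fibroblasts or from a response to them. If carried, genes at least 8 times higher at 0% oxygen would show the same share, yet of 28 such genes 18 (64.3%, exact 95% binomial interval 44.1% to 81.4%) had a share above 0, with a lower quartile of -0.921%. The first form of this test excluded carrying over when under 75% of shares were above 0, or when the lower quartile was below 0, so by that form it was excluded. The demand that the whole interval lie below 75%, the dropping of the condition on the quartile and a second test were set after that outcome was known, and with them the sources cannot be told apart. In the second test the median share was 1.23% for these genes (upper quartile 2.51%) against 2.57% for glycolysis genes (quartiles 1.64% to 2.94%).

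Fold changes beside other fibroblasts correlated between 0% and 10% fibroblasts across genes (0.123, and 0.099 with the block). Of 100 drawn splits, the real one included, 4 gave a correlation as high as 0.123 (highest other 0.146, median 0.0018), a margin too narrow to exclude chance firmly. Co-culture and control were also swapped only within replicate pairs, in the fit with the block. Of 100 drawn swaps 1 was as high as 0.099 (the real one, highest other 0.0845). By the rule for pairing, though, the numbers did not pair the 10% libraries, where 2 of 3 pairs were above 0.1. The interferon score was higher beside other fibroblasts at 0% oxygen (exact permutation p = 0.0286, two-sided, the difference falling from 1.10 to 0.64 without 1 library) and did not pass at 10% (0.171), and with an estimated correlation the list passed at neither (0.301 and 0.756). What both sides share is the device with a border, its handling and the parting of the regions, which may contribute as much as the neighbour's oxygen, and this cannot be tested here, since no device joined regions of equal oxygen.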
